A study of Danio rerio with 16 samples.

How the data were processed

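Gene expression was measured by RNA sequencing of skeletal muscle from adult zebrafish of the wild type strain AB (Oregon) and of a line carrying the ankrd1a allele bns502, made by CRISPR/Cas9 editing. Each library held RNA of 1 fish, and the 16 libraries fell into 4 groups of 4 by genotype and injury, as the sample labels state them. Injured fish had recovered for 5 days from a needle stab into the dorsal tail muscle, and the tissue around the lesion was taken; non-injured fish gave the matching region. Libraries were made from poly A RNA with a stranded kit, per the labels' protocols. The labels do not say where in ankrd1a the lesion lies or what it does to the transcript.

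The deposited table holds estimated counts per gene, the output unit of RSEM, for 32520 zebrafish genes. The tools named are fastp 0.23.4, STAR 2.7.0 and 2.7.10, and RSEM 1.3.3, per the submitters' processing notes, which do not say what each was used for. The genome build, the annotation and the strand setting are not given in the sources used here. Of all values, 94.29% were whole numbers, and 91.13% of those above 0 were. RSEM shares reads that fit several genes among them by probability. Therefore counts of near-identical genes (myosin heavy chains, troponins, other paralogs) are uncertain for each gene taken alone. All estimated counts deposited by the authors were rounded to whole numbers before testing. All 16 columns were matched to samples by the number that is both the column's name and the sample's description, and 0 columns were left over.

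Gene symbols came from a table pairing IDs with symbols, which named 29201 of the 32520 genes; 3319 had no symbol. Of these symbols 1806 are carried by more than 1 gene, covering 6314 IDs. Many zebrafish paralogs have there only the shared symbol of the human gene, in capitals. Symbols are printed as that table gives them, with the ID where the symbol is shared and the gene matters. The symbol ANKRD1 is carried by 2 IDs, which the table does not tell apart as ankrd1a and ankrd1b, so both are reported under their IDs.

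Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by the function filterByExpr with the 4 groups (a minimum count of 10 and a minimum total of 15), which left 16514. Library sizes were scaled by TMM (trimmed mean of M values). A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 16 libraries at once, with robust dispersion estimates, so that the groups shared their estimate of spread. The biological coefficient of variation was 31.3%. Contrasts were injured against non-injured in each genotype, mutant against wild type in each injury state, and the difference between the genotypes' injury responses (the interaction). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Every adjusted p for a gene comes from this edgeR test unless another tool is named, and all tests were two-sided. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM values are counts scaled to a common library size after TMM. Fish are the replicates.

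Gene lists, 26 in number, were fixed before the data were examined: 673 symbols, of which 640 matched a gene in the table by the exact symbol, by a synonym or, for paralogs, by the symbol without its suffix. Where a symbol was carried by 1 ID more than listed, all its IDs entered the list. Some lists therefore hold a gene that was not listed, as the cell cycle list with 34 symbols and 36 IDs. Lists were tested with camera (limma 3.58.1), which compares a list with all other genes. Camera was run with a preset correlation between genes of 0.01, which decides a list's call, and with an estimated correlation. The test fry, which asks if a list's genes move on balance 1 way, was run beside it. Adjustment was over the 26 lists within a contrast. A list's members were counted as called over all genes tested and, separately, with p-values adjusted over the list alone.

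The genes named in the text follow a rule that was also fixed then. Named are (a) ankrd1a, ankrd1b and ankrd2 throughout; (b) per contrast up to 10 called genes with the largest rise and up to 10 with the largest fall, among genes with a mean log2 CPM of at least 1, a symbol that is not a placeholder and, for contrasts of a pair of groups, no overlap between the 4 libraries on either side; (c) per contrast and list up to 4 called members with the smallest p, or the most highly expressed members where none was called, with lists summarised by their count where that suffices. Placeholder prefixes that are also the start of real symbols, such as CR, were read as clone names only where digits followed. Genes named outside this rule are said to be so.

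Total estimated counts ran from 17324482 to 25231102 per library. The tests were checked on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed in 1 group. For injury in wild type, 50 of 100 genes changed 2-fold and 87 of 100 changed 4-fold were recovered among 16210 tested, with 8 false calls among 145 calls. For the interaction, 13 of 100 genes changed 2-fold and 64 of 100 changed 4-fold were recovered among 16260 tested, with 2 false calls among 79 calls. For the contrast of injured mutant and injured wild type the recovery was 60 and 90 of 100 among 16248 tested, and without injury it was 48 and 88 of 100 among 16216. For injury in mutants it was 41 and 92 of 100 among 16247.

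Alternatives fixed before the data were examined were other scalings (DESeq2-style size factors, upper quartile, library size only), other tests (DESeq2 1.42.0, limma-voom with sample weights), no low count filter and a stricter one, an adjusted p below 0.01, a fold over 2, the replicate number as a block, a fit to only the 8 libraries compared, and each library left out in turn. Added after the data were seen were the level of the epidermis list as a covariate, the fits without the libraries highest in that list, and counts of neighbouring genes around ankrd1a. Which genes neighbour ankrd1a came from an NCBI RefSeq table for the assembly GRCz12tu, from which no coordinates are printed, since the authors' build is not given in the sources used here.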

Results

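The series asked which genes act downstream of ankrd1a while adult zebrafish muscle repairs a wound. Ankrd1 proteins are ankyrin repeat proteins of striated muscle whose transcripts are known to rise with stretch and damage. Muscle RNA was sequenced from 4 wild type and 4 mutant fish 5 days after a needle stab, and from 4 non-injured fish of each genotype. Total estimated counts per library were 22642566 ± 3205571 in non-injured wild type (mean ± SD, n = 4) and 23461820 ± 987292 in injured wild type. They were 18522729 ± 968812 in non-injured mutants and 17717586 ± 282392 in injured mutants, so mutant libraries were shallower. The most abundant gene in every library was myhc4, a fast myosin heavy chain. Log2 CPM values of libraries of 1 group correlated across genes with r between 0.918 and 0.966, and genes are not independent replicates.

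The transcript with the symbol ANKRD1 and the ID ENSDARG00000075263 rose after injury in both genotypes. In wild type it went from 3.53 ± 1.45 CPM (SD, n = 4) to 166 ± 19.4 CPM, a log2 fold change of 5.55 (SE 0.28, adjusted p = 1.8e-08). In mutants it went from 1.22 ± 0.155 to 132 ± 28 CPM, a log2 fold change of 6.74 (SE 0.31, adjusted p = 3.7e-09). Without injury it was lower in mutants by a log2 of -1.53 (SE 0.28, adjusted p = 0.01). That call was lost at an adjusted p of 0.074 when only the 8 non-injured libraries were fitted, and over all alternatives the adjusted p ran from 3.4e-05 to 0.074. After injury the genotypes differed by -0.33 (SE 0.23, adjusted p = 0.55), and the difference between the injury responses did not pass the test (1.2, SE 0.36, adjusted p = 0.42). The other ANKRD1 gene, ENSDARG00000076192, was scarce, with 0 to 2 counts in each non-injured library. It rose with injury to 0.808 ± 0.576 CPM in wild type (adjusted p = 0.0024) and 1.34 ± 0.374 CPM in mutants (adjusted p = 0.00063), and differed between genotypes in neither state (adjusted p = 0.98 without and 0.6 after injury). ANKRD2, a related gene, had between 0 and 4 counts per library and was not tested. The place of the lesion is not given in the sources used here, and the IDs could not be assigned to ankrd1a or ankrd1b. These levels therefore check nothing about the genotype labels.

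**Figure D1:**
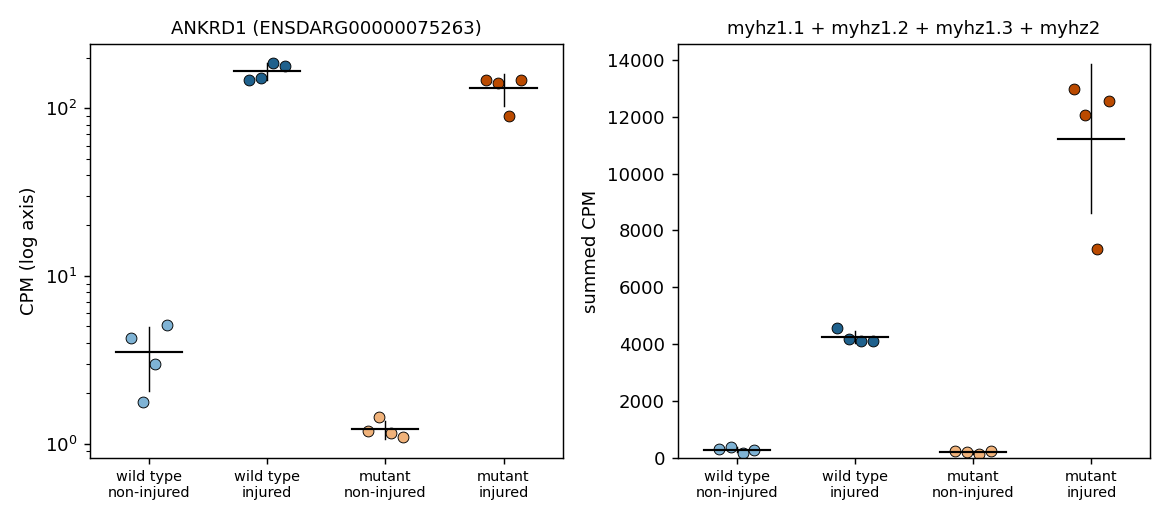
Left, CPM of ANKRD1 (ENSDARG00000075263) on a log axis; right, summed CPM of the myosin heavy chain genes myhz1.1, myhz1.2, myhz1.3 and myhz2 on a linear axis, by genotype and injury. Each point is 1 fish, the horizontal bar is the group mean and the vertical bar 1 SD (n = 4); ANKRD1 rose with injury in both genotypes, and all 4 injured mutants lay above all 4 injured wild types in the myosin sum.

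What injury changes in wild type muscle was the first comparison. Most listed matrix and cell cycle genes rose (36 of 50 and 27 of 34) and most listed mitochondrial genes fell (27 of 35). With an estimated correlation the adjusted p was 0.018 for the matrix list and 0.17 for the cell cycle and mitochondrial lists. Fast troponin and myosin genes were among the largest rises within the limits of the naming rule, which asks for a mean log2 CPM of at least 1 and no overlap between the groups. One was the fast troponin I gene TNNI2 (ENSDARG00000035958), from 0.631 ± 0.589 to 83 ± 16.2 CPM (log2 7.01, SE 0.49). The fast myosin gene myhz2 went from 120 ± 35.2 to 3200 ± 193 CPM (4.74, SE 0.27) and myhz1.1 from 10.7 ± 3.05 to 333 ± 181 CPM (4.97, SE 0.42). The troponin T gene TNNT3 (ENSDARG00000030270) had 0 counts in all 4 non-injured wild types and 48.6 ± 15.2 CPM after injury, at least 1240-fold higher than a floor of 3 counts over the group. Others were myhb (log2 6, SE 0.84), the thymosins tmsb (7.16, SE 0.40) and tmsb2 (4.68, SE 0.65), and txnb (5.67, SE 0.27). The growth factor MDK (ENSDARG00000036036) went from 5.82 ± 1.7 to 168 ± 62.9 CPM (4.86, SE 0.35). Within the same limits the largest falls were igfn1.2 (-3.13, SE 0.75), the glucocorticoid-responsive co-chaperone FKBP5 (-2.93, SE 0.95), RGCC (-2.53, SE 0.47), PIK3IP1 (-2.23, SE 0.29) and the mitochondrial carrier ucp3 (-2.17, SE 0.38). They were followed by PGPEP1L (-2.15), ASB14 (-2.14), SLC43A2 (-2.1), acss2l (-2.1) and ATP1B1 (-2.07).

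Extracellular matrix and remodelling genes had the smallest camera p of the lists raised in wild type. Of 50 measured members 36 rose and 0 fell (37 and 0 adjusted over the list alone), with a median log2 fold change of 1.19 (adjusted p = 0.018 with an estimated correlation). Examples were the collagens COL12A1 (ENSDARG00000019601; 2.99, SE 0.22), COL5A1 (1.93, SE 0.16) and COL6A3 (1.48, SE 0.13) and the proteoglycan LUM (2.87, SE 0.26). Of 34 cell cycle genes 27 rose and 1 fell (30 and 1 adjusted over the list alone), with a median of 1.93. Among them were TYMS (2.7, SE 0.39), CENPF (2.51), TOP2A (2.04) and CCNB1 (2.40). Of 24 satellite cell and myogenic regulators 9 rose and 1 fell (9 and 1 adjusted over the list alone). They included the fusion factor MYMK, from 0.0242 ± 0.0281 to 4.62 ± 1.02 CPM, MYOG (2.06, SE 0.21) and MEGF10 (1.04, SE 0.13). Of 22 cytokine and inflammatory signalling genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with SOCS3 (ENSDARG00000026611) at 2.46 (SE 0.22). Of 18 YAP-TEAD targets, which include both ANKRD1 genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone). Fast muscle contractile genes were split, with 8 of 31 up and 1 down (8 and 2 adjusted over the list alone). Their median was -0.03, or 0.29 with library size as the only scaling, while their mean was 1.28 (1.19 with TNNT3 at its bound), and camera took the direction of the mean. These 5 lists from the cell cycle on were called with the preset correlation but had an adjusted p = 0.17 each with an estimated correlation. Of 29 macrophage markers 11 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation), led by the transcription factor IRF8 (2.15, SE 0.24).

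In the other direction, 27 of 35 mitochondrial oxidative genes fell and 0 rose (33 and 0 adjusted over the list alone), with a median of -0.99. MDH2 (-1.26, SE 0.17) and the complex I subunit NDUFS3 (-1.38, SE 0.22) were examples. Of 26 glycolysis genes 15 fell and 0 rose (15 and 0 adjusted over the list alone), with GAPDH at -1.28 (SE 0.25) and PKM (ENSDARG00000099860) at -1.18 (SE 0.18). Of 18 slow muscle genes 9 fell and 1 rose (14 and 1 adjusted over the list alone), with the slow troponin tnni1c at -1.21 (SE 0.23). Of 24 endothelial markers 11 fell (13 adjusted over the list alone). These 4 lists had an adjusted p = 0.17 each with an estimated correlation. Nerve and Schwann markers (5 of 24 fell, also adjusted over the list alone) and protein breakdown genes (10 of 22 fell and 3 rose, also adjusted over the list alone) had an adjusted p = 0.26 each with an estimated correlation. Of 30 circadian clock genes 12 fell and 4 rose (15 and 6 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation), and their median of -0.38 became 0 with library size as the only scaling.

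Lists not called in wild type were the stretch and stress genes (camera adjusted p = 0.089), neutrophil (0.089), lymphocyte (0.11), interferon (0.62), immediate early (0.052), heat shock (0.65), calcium handling (0.11), epidermis (0.88), bone and scale (0.15), adipocyte (0.62), pigment (0.54) and erythrocyte (0.62) lists. Among these the median and the mean or the test differed in sign for the heat shock and adipocyte lists. In total 1956 genes rose and 1971 fell of 16514 tested in wild type. With library size as the only scaling the median gene moved up by a log2 of 0.36 and the split became 3673 up and 537 down, so directions are relative to the median gene. The count was 2608 without injured wild type replicate 2 and 2565 in a fit of only the 8 wild type libraries. Of the 20 genes with the largest changes, 18 kept their call without any 1 library. FKBP5 (adjusted p up to 0.11) and ATP1B1 (up to 0.059) lost theirs, both at most without injured wild type replicate 2. Beyond single libraries, igfn1.2 lost its call with only the 8 libraries compared (0.052). FKBP5 lost its call with library size only (0.058), no low count filter (0.078) and the epidermis covariate (0.065), and ATP1B1 with limma-voom (0.059). Without the libraries highest in epidermis markers FKBP5 (0.073) and ATP1B1 (0.09) lost theirs too.

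**Figure D2:**
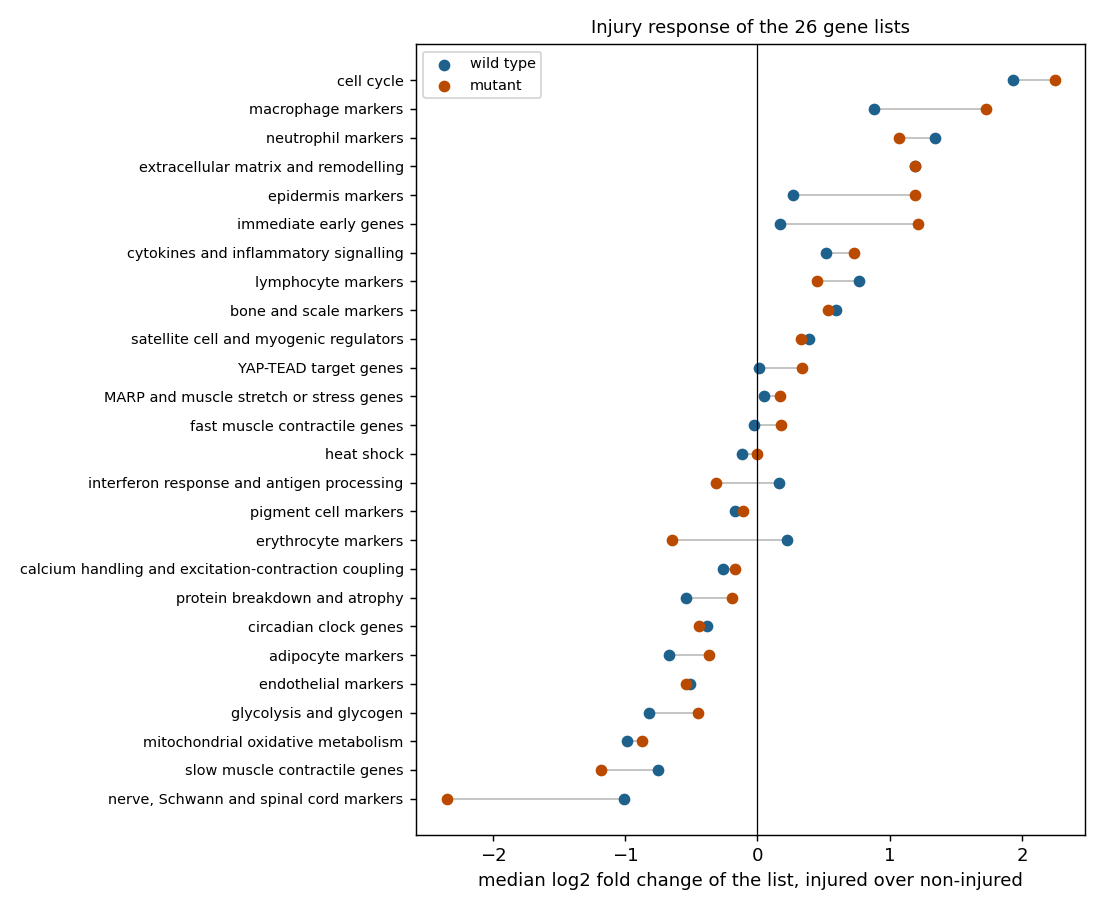
Median log2 fold change after injury (horizontal axis) of each of the 26 gene lists (vertical axis) in wild type and in mutant muscle, from 4 injured and 4 non-injured fish per genotype; grey lines join the genotypes. Matrix genes had a median of 1.19 in both genotypes, and immediate early genes 0.17 in wild type and 1.21 in mutants; no error bars are drawn.

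In mutants, most listed matrix (34 of 50), cell cycle (30 of 34) and macrophage genes (24 of 29) rose after injury, and most listed mitochondrial (26 of 35) and slow muscle genes (13 of 18) fell. With an estimated correlation the matrix (adjusted p = 0.028) and slow muscle (0.047) lists of these were called, while the cell cycle (0.062), macrophage (0.18) and mitochondrial (0.24) lists were not. Within the limits of the naming rule the fast myosins myhz1.1, from 8.5 ± 1.97 to 1712 ± 623.5 CPM (log2 7.66, SE 0.47), and myhz2, from 98.4 ± 19 to 6990 ± 1510 CPM (6.15, SE 0.28), were among the largest rises. TNNI2 (ENSDARG00000035958) reached 134 ± 25.8 CPM (7.68, SE 0.50). TNNT3 (ENSDARG00000030270) had 0.0404 ± 0.0808 CPM without injury and 73 ± 24.3 CPM after it (adjusted p = 5.6e-07). The actins ACTC1 (6.19, SE 0.76) and ACTA1 (ENSDARG00000036371; 5.47, SE 0.76), tmsb (6.22, SE 0.35), txnb (5.19, SE 0.26) and the apolipoprotein apoc1 (5.72, SE 1.28) rose too. Falls were led by igfn1.2 (-4.89, SE 0.95), the autophagy receptor CALCOCO1 (ENSDARG00000016391; -3.10, SE 0.84), klhl33 (-2.77, SE 0.43), hmga1b (-2.34) and the growth hormone receptor ghrb (-2.33). METTL21C (-2.32), the slow troponin tnni1c (-2.27, SE 0.23), cldc1 (-2.27), CRABP1 (-2.23) and the cytochrome oxidase gene cox4i1l (-2.22, SE 0.21) followed.

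Of the lists in mutants, 34 of 50 matrix genes rose and 1 fell (37 and 1 adjusted over the list alone; adjusted p = 0.028 with an estimated correlation). Of 34 cell cycle genes 30 rose and 1 fell (31 and 1 adjusted over the list alone; adjusted p = 0.062 with an estimated correlation). Of 29 macrophage markers 24 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.18 with an estimated correlation), with MPEG1 (ENSDARG00000055290) at 2.37 (SE 0.36) and the complement gene c1qb at 2.30 (SE 0.39). This list's mean log2 CPM went from 1.87 ± 0.17 to 3.82 ± 0.28 in mutants and from 2.52 ± 1.03 to 3.65 ± 0.62 in wild type (SD, n = 4). The levels after injury were thus close, and non-injured wild types were widely spread. Of 29 immediate early genes 17 rose and 0 fell (18 and 0 adjusted over the list alone; adjusted p = 0.078 with an estimated correlation). They included FOSL1 (3.78, SE 0.47), FOSL2 (3.64, SE 0.44), DUSP5 (2.73, SE 0.32) and JUNB (ENSDARG00000104773; 2.37, SE 0.31). YAP-TEAD targets (7 of 18 up, 1 down; adjusted p = 0.029 with an estimated correlation), fast muscle genes (9 of 31 up, 2 down; 0.055) and satellite and myogenic genes (9 of 24 up, 1 down; 0.065) had the same counts adjusted over the list alone. Cytokines had 8 of 22 up (9 up and 1 down adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), and stretch genes 4 of 19 up, also adjusted over the list alone (0.41). Epidermis markers were called higher as a list (median 1.19, camera adjusted p = 0.02; 0.54 with an estimated correlation), though edgeR called 0 of 19 members, also adjusted over the list alone. DESeq2 called 1 of these 19, and 2 had an unadjusted p below 0.05.

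Among the lists that went down in mutants were slow muscle genes, with 13 of 18 lower, also adjusted over the list alone (adjusted p = 0.047 with an estimated correlation). Of 35 mitochondrial genes 26 fell (31 adjusted over the list alone) and of 26 glycolysis genes 9 (the same adjusted over the list alone), each list with an adjusted p = 0.24 with an estimated correlation. Of 24 nerve markers 17 fell (21 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Endothelial markers (11 of 24 down, 1 up, also adjusted over the list alone) had an adjusted p = 0.078 with an estimated correlation. Clock genes (12 of 30 down and 4 up; 12 and 5 adjusted over the list alone) had 0.39. Not called were calcium handling (camera adjusted p = 0.093), protein breakdown (0.093), neutrophil (0.12), lymphocyte (0.21), interferon (0.28), heat shock (0.87), bone (0.093), adipocyte (0.59), pigment (0.83) and erythrocyte (0.075) lists. For the interferon, adipocyte and heat shock lists the median, mean and test differed in sign. In mutants 2306 genes rose and 2190 fell. With library size only the median gene moved by 0.27 and the split was 3108 up and 779 down, and with the epidermis level as a covariate 2695 genes were called. CALCOCO1 fell to -2.08 and lost its call with that covariate (adjusted p = 0.1), and lost it (0.052) without non-injured mutant replicate 4, while the other 19 of the 20 largest changes kept theirs without any 1 library.

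Set against each other, the injury responses of the genotypes overlapped widely. In both, 1371 genes rose and 1279 fell, where independent lists would share 273.1 and 261.4, and 7 genes were called in opposite directions. Of the genes called in wild type, 97.1% had the same sign in mutants. Across all genes tested the log2 fold changes correlated with r = 0.65 (Spearman rho 0.69). The contrasts share no library.

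Without injury, mutant muscle differed from wild type muscle in 467 genes, 228 higher and 239 lower in mutants. Within the limits of the naming rule the largest rises were in the tumour necrosis factor receptor tnfrsf1b, from 5.24 ± 2.74 to 29.5 ± 7.02 CPM (log2 2.49, SE 0.57), and in the peroxisomal membrane gene PXMP4 (2.41, SE 0.24, adjusted p = 8.3e-05). Next were cox6b1 (2.35, SE 0.40), RNASEK (ENSDARG00000104458; 2.30, SE 0.34), SERF2 (2.23), POGLUT2 (2.02), the lectin ITLN1 (2), FAM184A (1.87), UNC93B1 (1.81) and CBS (1.75). The largest fall within these limits was in the F-box gene fbxo44.9, from 7.91 ± 1.24 to 0.264 ± 0.0869 CPM (-4.87, SE 0.60). The integrin alpha gene itgam.1 (-3.00, SE 0.27, adjusted p = 4.1e-05), fbxo44.10 (-2.85, SE 0.38), arhgef18a (-2.82), MFAP4 (ENSDARG00000088745; -2.7), RHPN2 (-2.18), ANKRD9 (-2.04), the kinase SIK1 (-1.95), gstt2 (-1.94) and dap1b (-1.90) were also lower.

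Among list members without injury, the immediate early genes klf2a (-0.93, SE 0.15), JUND (-1.15, SE 0.23) and FOSB (-1.84, SE 0.41) were lower in mutants and 0 of 29 were higher (8 lower and 1 higher adjusted over the list alone). Of 30 clock genes 2 were higher and 3 lower (4 and 5 adjusted over the list alone), with PER2 (0.88, SE 0.16) higher and dbpb (-0.81, SE 0.13) and ciarta (-0.76, SE 0.13) lower. Of 50 matrix genes 2 were higher and 3 lower (2 and 7 adjusted over the list alone), and 42 had a negative log2 fold change. The 2 were the IDs of the collagen chaperone SERPINH1 (ENSDARG00000019949 0.88, SE 0.16; ENSDARG00000075954 0.75, SE 0.16), and the 3 were THBS1 (ENSDARG00000103775; -1, SE 0.19), LOXL2 (-0.56, SE 0.13) and MMP14 (ENSDARG00000008388; -0.71, SE 0.18), the last of them outside the naming rule and chosen after its values were seen. The matrix list as fixed named only serpinh1b, so 1 of the 2 SERPINH1 IDs was not listed there. The heat shock list named both paralogs. Of 24 satellite and myogenic genes 2 were higher and 0 lower (2 and 1 adjusted over the list alone), among them MYF5 (0.81, SE 0.17), and of 22 protein breakdown genes 1 was lower, MAP1LC3B (-0.96, SE 0.16), and 0 higher (2 and 0 adjusted over the list alone). Camera called fast muscle, matrix, macrophage, neutrophil, cytokine, immediate early, epidermis and bone lists lower, and slow muscle, lymphocyte and heat shock lists higher, 11 in all. With an estimated correlation 0 lists were called: the adjusted p was 0.45 for the fast muscle, matrix, neutrophil, lymphocyte, cytokine, immediate early and heat shock lists, 0.52 for epidermis, 0.55 for slow muscle, 0.56 for bone and 0.62 for macrophages. Beside these calls, the epidermis list was at 3.61 ± 1.12 mean log2 CPM in non-injured wild type and 1.91 ± 1.2 in non-injured mutants (SD, n = 4). The median, mean and test differed in sign for the stretch, satellite and adipocyte lists, which were not called.

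The count without injury moved with the fit. It was 130 in a fit of only the 8 libraries, 159 with the epidermis level as a covariate, 299 without the libraries highest in that list, 280 with limma-voom and 1135 with DESeq2. Leaving out wild type replicate 3 gave 244, mutant replicate 2 gave 267 and mutant replicate 3 gave 172. With library size only the median gene moved by 0.22 and the split was 347 up and 76 down. Of the 20 genes with the largest changes 12 kept their call without any 1 library. Calls were lost without mutant replicate 3 for tnfrsf1b (adjusted p = 0.088), dap1b (0.10), LOXL2 (0.12), JUND (0.061) and MYF5 (0.067). Without wild type replicate 3 they were lost for POGLUT2 (0.06), ITLN1 (0.093), FAM184A (0.071), CBS (0.079), gstt2 (0.10), FOSB (0.089) and SERPINH1 (ENSDARG00000075954; 0.081), and without mutant replicate 1 for SERF2 (0.073). Each value is the highest over the 8 fits, and the library named is the one left out there. Several calls were lost in other fits too. Those of ITLN1 and gstt2 were lost in all 8 fits, and those of tnfrsf1b and dap1b in most. With limma-voom the calls of fbxo44.9 (0.14), MFAP4 (0.11), tnfrsf1b (0.14), POGLUT2 (0.1), ITLN1 (0.24), CBS (0.12), gstt2 (0.1), dap1b (0.1) and FOSB (0.13) were lost. With only the 8 libraries those of cox6b1 (0.056), SERF2 (0.2), POGLUT2 (0.058), FAM184A (0.12), UNC93B1 (0.075), CBS (0.052), RHPN2 (0.067), gstt2 (0.1), dap1b (0.11), LOXL2 (0.12), THBS1 (0.07), JUND (0.057), MYF5 (0.11) and both SERPINH1 IDs (0.058 and 0.15) were. With the epidermis covariate those of tnfrsf1b (0.1), SERF2 (0.12), POGLUT2 (0.084), ITLN1 (0.11), CBS (0.1), gstt2 (0.13), dap1b (0.062), LOXL2 (0.16), THBS1 (0.076), FOSB (0.097) and MYF5 (0.07) were. With library size only those of dbpb and ciarta (each at most 0.095), LOXL2 (0.33), THBS1 (0.067), FOSB (0.062), gstt2 (0.11) and dap1b (0.053) were, and other alternatives ended calls of tnfrsf1b, SERF2, POGLUT2, ITLN1, CBS, LOXL2, FOSB, gstt2 and dap1b. MMP14, at an adjusted p of 0.0495, was not followed over the alternatives.

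After injury, 3 fast myosin heavy chain genes were higher in mutants than in wild type, while myhc4, the most abundant one, was not (-0.38, SE 0.30, adjusted p = 0.62). The fast muscle list had 3 of 31 members higher and 0 lower (5 and 0 adjusted over the list alone), a median of -0.15 (0.01 with library size only), and was not called. The log2 difference was 2.36 for myhz1.1 (SE 0.37, adjusted p = 0.004), 2.02 for myhz1.2 (SE 0.36; 101 ± 28.6 CPM in wild type and 409 ± 164 CPM in mutants) and 1.13 for myhz2 (SE 0.23, adjusted p = 0.022). Because reads of these genes can be shared, their counts were summed with those of myhz1.3, after the 3 genes had been called. The sum was 4248 ± 224 CPM in injured wild type and 11236 ± 2629 CPM in injured mutants (SD, n = 4), 2.58-fold higher by the mean of logs. Every mutant lay above every wild type in the sum as in myhz2 alone, so the sum is no separate test of the difference. Other rises were znf1179 (5.23, SE 1.02), CCDC92 (3.33, SE 0.31), the non-coding RNA gas5 (2.40, SE 0.24), the repressor snai3 (2.38), wfdc2 (2.18), RNASEK (ENSDARG00000104458; 2.1), CLN8 (2.01) and selenol (1.95). Of the matrix list THBS4 (ENSDARG00000020072; -1.32, SE 0.20), LOXL1 (-0.95, SE 0.17) and DCN (-0.76, SE 0.15) were lower in mutants. Also lower were bcan (-1.63), CLEC3B (-1.62), PIGP (-2.39), DGLUCY (-1.95, SE 0.17), itgam.1 (-1.76), trim105 (-1.48), RASL12 (-1.45), NUS1 (-1.36) and GFER (-1.30). In total 137 genes were higher and 107 lower.

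Of 50 matrix genes 3 were lower and 0 higher after injury (8 and 2 adjusted over the list alone). Of 24 satellite and myogenic genes CDH15 (0.85, SE 0.15) and jam2a (0.70, SE 0.14) were higher and 0 lower (4 and 1 adjusted over the list alone). Camera called matrix, slow muscle, neutrophil, cytokine, nerve, bone and erythrocyte lists lower in mutants, and satellite, mitochondrial, cell cycle, lymphocyte, immediate early and heat shock lists higher, 13 in all. With an estimated correlation 0 lists were called, the adjusted p being 0.55 for cell cycle and 0.53 for each of the others. The median, mean and test differed in sign for the fast muscle, interferon and adipocyte lists, which were not called. The count after injury was 386 in a fit of only the 8 injured libraries, 712 with DESeq2, 889 with limma-voom and 134 without the libraries highest in epidermis markers. It fell to 116, 106 and 135 without injured wild type replicates 1, 2 and 3, and to 157, 135 and 123 without injured mutant replicates 2, 3 and 4. With library size only the median gene moved by 0.13 and 154 genes were up and 54 down. Of the 20 genes with the largest changes 12 kept their call without any 1 library. Calls were lost without injured wild type replicate 1 for znf1179 (adjusted p = 0.08) and myhz2 (0.07), and without replicate 2 for snai3 (0.072), myhz1.2 (0.05), bcan (0.11), DCN (0.07) and jam2a (0.07). Without injured mutant replicate 3 they were lost for PIGP (0.13), CLEC3B (0.06) and NUS1 (0.077), and without replicate 2 for GFER (0.076). Each value is the highest over the 8 fits, and the library named is one left out there. Several calls were lost in other fits too, those of PIGP, bcan, NUS1 and GFER in most of the 8. With library size only the calls of PIGP (0.07), bcan (0.075), CLEC3B (0.079), GFER (0.079), LOXL1 (0.064) and DCN (0.093) were lost. Without the libraries highest in epidermis markers those of znf1179 (0.076), snai3 (0.051), PIGP (0.11), bcan (0.069), GFER (0.057), myhz2 (0.076), DCN (0.08) and jam2a (0.08) were. With limma-voom that of znf1179 (0.053) was lost, with only the 8 libraries those of PIGP (0.068) and bcan (0.052), without a low count filter that of PIGP (0.074), and with the replicate block those of snai3 (0.055), PIGP (0.05), CLEC3B (0.053) and DCN (0.05).

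Genotype differences recurred in both injury states. In each, 47 genes were higher and 36 lower in mutants, where independent lists would share 1.9 and 1.5, and 0 were called in opposite directions. The log2 differences correlated across all genes with r = 0.46 (Spearman rho 0.44), and these contrasts share no library. Both set the same mutant line against the same wild type strain, and mutant libraries were shallower in both states. Recurrence alone therefore does not assign the differences to ankrd1a.

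Whether the genotypes respond differently to injury was tested as an interaction. CCDC92 fell in wild type from 3.08 ± 1.19 to 1.15 ± 0.225 CPM and rose in mutants from 2.56 ± 0.816 to 11.6 ± 3.25 CPM (interaction log2 3.59, SE 0.42, adjusted p = 0.0025). The calcineurin regulator rcan1a stood at 20.1 ± 0.889 and 23.3 ± 5.27 CPM in wild type, and at 15.2 ± 1.07 and 59.7 ± 13.7 CPM in mutants (1.75, SE 0.25, adjusted p = 0.0099). TRHDE (ENSDARG00000109358) rose more in mutants (1.42, SE 0.19). DGLUCY went from 4.05 ± 0.721 to 16.3 ± 2.8 CPM in wild type and from 4.83 ± 0.608 to 4.21 ± 0.74 CPM in mutants (-2.20, SE 0.25). These 4 genes kept their call without any 1 library, but with library size only rcan1a (1.66) and TRHDE (1.35) lost theirs, each at an adjusted p of 0.12. SERPINH1 (ENSDARG00000019949) went from 26.3 ± 6.1 to 69.2 ± 9.32 CPM in wild type and from 48.5 ± 4.59 to 51.6 ± 6.95 CPM in mutants (-1.31, SE 0.23, adjusted p = 0.0499). It lost its call in 14 of 16 fits without 1 library, with an adjusted p of up to 0.16 without non-injured mutant replicate 2, and with library size only (0.12), upper quartile (0.053), the stricter filter (0.065), the replicate block (0.07), the epidermis covariate (0.1) and without the libraries highest in epidermis markers (0.11). In all 10 genes were called, 3 up and 7 down, against 1207 with an unadjusted p below 0.05. DESeq2 called 62, limma-voom 6, the replicate block 4, the epidermis covariate 5 and the stricter filter 6. The count was 5 without any 1 of non-injured wild type replicates 3 or 4, injured wild type replicates 3 or 4, and non-injured mutant replicates 1 or 3. It was 6 without injured wild type replicate 2, non-injured mutant replicate 2 or injured mutant replicate 1. With library size only 1 gene was up and 5 down.

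By list, immediate early genes had a higher median response in mutants (median interaction log2 1.11, camera adjusted p = 1.1e-11; adjusted p = 0.14 with an estimated correlation). EdgeR called 0 of 29 members (5 higher and 0 lower adjusted over the list alone), DESeq2 called 3, and 13 had an unadjusted p below 0.05. The list's mean log2 CPM was 2.44 ± 0.16 without and 3.05 ± 0.22 with injury in wild type, and 1.89 ± 0.22 and 3.39 ± 0.36 in mutants (SD, n = 4). Epidermis markers were at 3.61 ± 1.12 and 3.61 ± 1.47 in wild type, and at 1.91 ± 1.2 and 3.43 ± 0.69 in mutants. Camera also called fast muscle, cell cycle, macrophage, YAP-TEAD and epidermis lists higher and slow muscle, interferon, nerve and erythrocyte lists lower. With an estimated correlation 0 lists were called, and the adjusted p of these ran from 0.14 for the YAP-TEAD list to 0.89 for cell cycle. Among lists not called, the median, mean and test differed in sign for the calcium handling, matrix, neutrophil, heat shock, clock, endothelial and adipocyte lists.

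**Figure D3:**
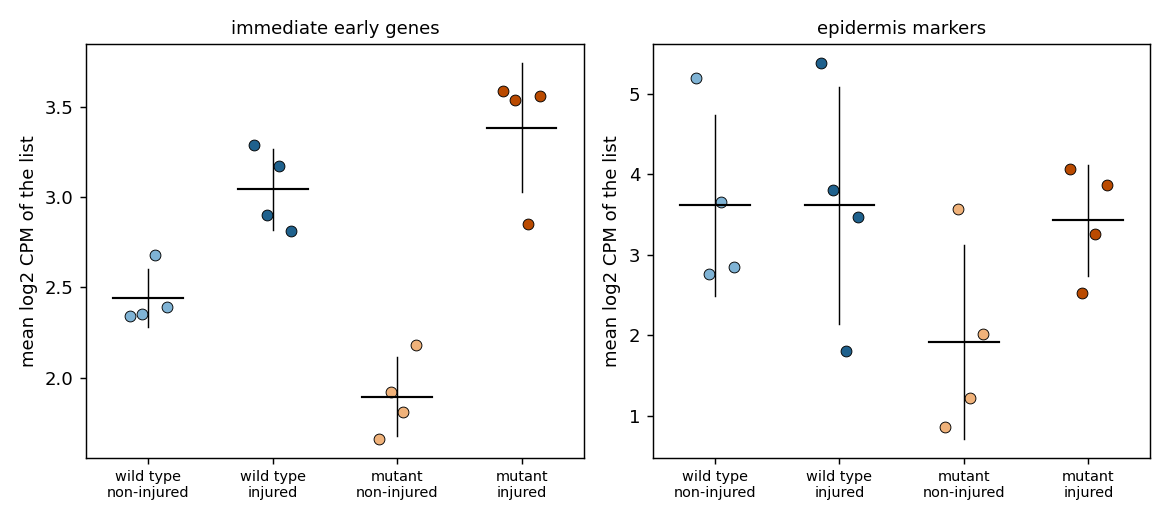
Mean log2 CPM of the immediate early gene list (left) and the epidermis list (right) by genotype and injury. Each point is 1 fish, the horizontal bar is the group mean and the vertical bar 1 SD (n = 4); early genes went from 1.89 to 3.39 in mutants, and epidermis markers ran from 0.86 to 5.38 over the 16 libraries.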

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

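The 3 patterns weighed here and the fits with the epidermis or macrophage level as a covariate were chosen after the calls were seen, with bounds written before those fits were run; chosen after these results too were the test of how much of their size the differences without injury keep with the epidermis level in the model, the stricter bound on linked variation that counts genes without a place, the counts of genes near ankrd1a, the repeats of the thinning after a first draw, the splits of the genotype labels, the comparison with myosins outside the sum, and the look at the 100 genes with the largest injury rise.

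Libraries far from the other 3 of their group were looked for in 122 groups of values, of which chance would give about 6.1, and 7 were found. Injured mutant replicate 3 accounted for 4, each below the other injured mutants. Its summed fast myosin level was 7333.8 CPM, its ANKRD1 (ENSDARG00000075263) level 90 CPM, its stretch and stress list 5.46 and its immediate early list 2.85 mean log2 CPM. Non-injured wild type replicate 3 stood apart in immediate early genes (2.68) and injured wild type replicate 3 in satellite genes (3.42). Injured mutant replicate 4 had the only ANKRD2 count of its group (0.0502 CPM).

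The 10 genes whose injury response differed between genotypes by the interaction test had log2 values of 3.59 (CCDC92), 1.75 (rcan1a), 1.42 (TRHDE), -2.20 (DGLUCY), -1.31 (SERPINH1), -2.71 (si:ch211-207c6.2), -4.23 (ENSDARG00000100540), -5.23 (znf1094), -5.75 (si:dkey-28g23.6) and -8.64 (si:dkey-201g16.6). The last 5 fall outside the naming rule and were named after their values were seen. The last value is a fitted one that rests on very few counts in non-injured wild type and injured mutants, and its size depends on the model's prior count. The 10 lists called in that test had medians of 1.11 (immediate early), 0.86 (epidermis), 0.60 (macrophage), 0.33 (cell cycle), 0.27 (YAP-TEAD), 0.23 (fast muscle), -0.29 (interferon), -0.53 (slow muscle), -1.05 (nerve) and -1.05 (erythrocyte).

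Other splits of the libraries bear on all 5 counts. Of the 35 splits of the 8 libraries, 1, the real one, called as many genes in each contrast of a pair of groups. That is the smallest share 35 splits can give, so chance is made unlikely for these counts but is not excluded. The real counts and the highest of the other splits were 3927 and 492 for injury in wild type, 4496 and 1 for injury in mutants, 467 and 129 for genotype without injury, and 244 and 1 for genotype after injury. For the interaction, 4 of 100 splits of the injury labels within each genotype, the real one included, called at least the real 10. These splits put the injury response into the spread (82 called 0 genes) or into the contrast, so they decide nothing about chance. The highest of them called 3724 genes and points to a structure of the samples. It nearly exchanged the injury labels within wild type while keeping those of the mutants, so the injury response itself entered the contrast. Splits of the genotype labels within each injury state leave the injury response in place. Of 100 of these 1, the real one, called as many as 10, and the highest other called 4. They put the genotype differences into the spread, however (94 called 0 genes), so they cannot exclude chance for the interaction.

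Linked variation, depth or skin could enter the genes that differ between mutant and wild type, but the first does not account for most calls: even if every call without a place lay on the ankrd1a chromosome its share would be 37.3% (exact 95% interval 32.9 to 41.8) without and 42.2% (35.9 to 48.7) after injury. These shares are upper limits counted over the calls made here. Their intervals treat genes as independent draws and hold no spread between fish. A smaller contribution stays open, since among placed genes 6.52% of the nearest 200 on either side of ankrd1a were called without injury against 2.65% elsewhere (Fisher p = 0.012), after injury 12.2% of calls at an adjusted p below 0.01 lay on the chromosome (odds ratio 3.55, p = 0.019), the other 10 such tests had p from 0.07 to 1, and ANKRD9, CLN8 and DGLUCY lie there. With every library thinned to 17324482 counts, a mean of 84.6% of calls stayed (79.4 to 88 over 20 draws) without and 86.6% (79.1 to 90.6) after injury. At this equal depth a mean of 434.2 and 229.1 genes were called, against 467 and 244. These values argue against unequal depth as the source of most calls. The lowest draws fell under the 80% set beforehand, so depth is not excluded for single calls. After injury the epidermis level was near equal as a mean of log2 CPM (3.61 ± 1.47 in wild type and 3.43 ± 0.69 in mutants). By edgeR's fold changes the list had a median log2 of -0.67 in injured mutants, with 12 of 19 members below 0 and 0 called. The injured mutants (2.53 to 4.06) lay within the range of the injured wild types (1.8 to 5.38). With that level as a covariate 91% of calls stayed, with a median 100% of their log2 fold change (10th to 90th percentile 98.5 to 101.6). A near-equal level can hardly move a fit, so these shares were largely fixed beforehand and cannot decide about skin. Of the 244 calls, 122 stayed without the libraries highest in epidermis markers, a fit with fewer samples. Unequal skin therefore stays open for the calls after injury. Without injury 29.6% (138 of 467) stayed with the covariate, under the 50% written before that fit as the mark of skin as a cause. In the test added afterwards these genes kept a median 98% of their log2 fold change (10th to 90th percentile 81.1 to 114.2). The median size was 1.14 (SD 1.44) before and 1.12 (SD 1.42) after, and calls ended as standard errors grew 1.16 times. The share of calls kept therefore cannot tell skin from lost precision, while the sizes argue against skin as what sets most of these differences. A smaller share of skin cannot be told from genotype there, as the epidermis level was lower in non-injured mutants.

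Immediate early genes may respond more to injury in mutants, a hypothesis found and tested on the same data. The list's mean log2 CPM without injury was 2.44 ± 0.16 in wild type and 1.89 ± 0.22 in mutants. After injury it was 3.05 ± 0.22 and 3.39 ± 0.36. EdgeR called 3 of 29 members lower in mutants without injury, and 0 in either direction after it. A lower level in non-injured mutants is therefore part of the pattern. The pattern did not rest on 1 library, as without each of the 16 in turn the unadjusted camera p with an estimated correlation was at most 0.019. With all 16 the camera p adjusted over the lists was 0.14, also with an estimated correlation. These fits therefore do not establish the difference. The median interaction of 1.11 became 0.97 with the epidermis covariate, which argues against skin as the whole cause. It became 0.71 with the macrophage covariate, between the bounds set beforehand, so a share from unequal macrophage content stays open, as does the genotype itself.

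The genes myhz1.1, myhz1.2 and myhz2 may be higher in injured mutants, again as a hypothesis. Reads moved among the 4 summed genes would leave their sum unchanged, and it differed by a log2 of 1.37, but a shift of reads from myhc4 or myha stays open: the sum gained 6988 CPM, 20.4% of the SD of those genes in injured wild type (131013 ± 34298 CPM, and 105550 ± 17076 CPM in injured mutants, n = 4). More wound tissue would raise injury genes in general. The 1371 genes raised over 2-fold by injury on average had a median mutant difference of 0.01 (95% bootstrap interval -0.03 to 0.04). For the 100 with the largest rise it was 0.17 (-0.25 to 0.46). Both intervals come from resampling genes, which are not independent replicates, and hold no spread between fish. The median of the 1371 shows no general rise, but more wound tissue is not excluded. These 1371 are not the 1371 genes called up in both genotypes, with which they share 829. Differences in the pace of regeneration and in the genetic background of the lines were not tested.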

How the results depend on the processing

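The epidermis covariate, the gene counts around ankrd1a and the fits without the libraries highest in epidermis markers (wild type replicate 1 in both injury states) were chosen after seeing the data, as were the repeats of the thinning after a first draw. No called change of a named gene or ANKRD1 and no called list's test changed direction under any alternative run. List medians did: with library size only that of fast muscle in wild type injury went from -0.03 to 0.29, and among lists not called, calcium handling went from -0.26 to 0.12 in wild type and -0.17 to 0.13 in mutant injury, and others changed sign too. An adjusted p below 0.01 left 1911, 2374, 83, 68 and 5 genes for injury in wild type, injury in mutants, genotype without injury, genotype after injury and the interaction. A fold over 2 left 1659, 2044 and 269 in the first 3. Fits of only the 8 libraries compared gave 2565, 130 and 386 for injury in wild type and the genotype contrasts without and after injury; separate dispersion estimates and fewer libraries go with that change, and the cause was not tested. DESeq2 called 1135, 712 and 62 genes and limma-voom 280, 889 and 6 in the genotype contrasts and the interaction; the cause was not tested. The epidermis covariate gave 2695 for injury in mutants, 159 for genotype without injury and 5 for the interaction, and the fits without the epidermis-high libraries, which hold fewer samples, 299 and 134 for the genotype contrasts. The interaction was 6 with library size only and 6 with the stricter filter; the cause was not tested.

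Leaving out 1 library gave 2608 to 4205, 3524 to 4120, 172 to 625, 106 to 266 and 5 to 13 genes in the same order. ANKRD1 (ENSDARG00000075263) without injury had a log2 of -1.54 and lost its call (adjusted p = 0.074) with only 8 libraries; over all alternatives its adjusted p ran from 3.4e-05 to 0.074. Camera with an estimated correlation called 1, 3, 0, 0 and 0 lists, against 14, 16, 11, 13 and 10 with the preset. Fry called 0 in the last 3 but most of the 26 lists for injury in each genotype. Its adjusted p for injury in wild type was 0.00023 for the cell cycle list and 0.0011 for the mitochondrial list. In mutants it was 0.0013 for the macrophage list and 0.003 for the mitochondrial list. Fry does not compare a list with other genes, as camera does. The replicate number as a block gave 3653, 4274, 383, 164 and 4 genes; of 24 same-numbered pairs 8 correlated over 0.1 (median 0.04), and 6 of 16 libraries correlated best with their own number, so the numbers are not read as pairs. The 5 Mb and 10 Mb windows around ankrd1a were not run, since the build is not given in the sources used here; gene counts on either side stood in for them. At the real depths and numbers of fish, simulated 2-fold changes were found in 13 of 100 genes for the interaction, and thinning kept a mean of 70% of its calls.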

Other observations

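No test here was chosen after a result was seen, but the genes in the first paragraph were picked after their values were seen. MYL9, a myosin regulatory light chain, was higher in mutants by a log2 of 1.41 (SE 0.17, adjusted p = 0.00056) without injury and 1.59 (SE 0.18, adjusted p = 0.00021) after it, in edgeR's test. The neurotensin receptor NTSR1 was higher by 4.29 (SE 0.56) and 3.92 (SE 0.56), and the transcription factor tbx6 lower by -4.30 (SE 0.48) and -4.26 (SE 0.44). Both genes were scarce, under the naming rule's minimum of 1 in mean log2 CPM. EdgeR's own average log2 CPM was 1.16 for NTSR1 and 0.11 for tbx6. Neither was followed over the alternatives. Near-equal differences with and without injury were also seen for dbpb, a clock output gene (-0.81 and -0.79), and MAP1LC3B (-0.96 and -0.89).

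The leptin genes, in the adipocyte list, rose with injury in both genotypes. The gene lepb went from 0.0516 ± 0.103 to 2.34 ± 1.22 CPM in wild type (SD, n = 4; edgeR adjusted p = 0.00046) and from 0.0134 ± 0.0267 to 1.41 ± 0.519 CPM in mutants (adjusted p = 0.00049). The gene lepa had 0 counts in all non-injured fish and was at least 18.1-fold higher in injured wild types and at least 37.7-fold higher in injured mutants than a floor of 3 counts over the group. In the same list LPL (ENSDARG00000087697) fell by 1.51 (SE 0.37) and 1.52 (SE 0.37) on the log2 scale, and ADIPOQ (ENSDARG00000100086) by 1 (SE 0.30) and 1.49 (SE 0.31). The ADIPOQ call in wild type was lost in 5 of 8 fits without 1 library, at most (adjusted p = 0.11) without non-injured wild type replicate 4.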
